A study of Mus musculus with 6 samples.

How the data were processed

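The material was RNA from the hippocampus of male DBA/2 mice, 10 animals per dose group, combined into 1 left and 1 right pool for each of 3 venlafaxine doses. Per the labels, 100 ng of total RNA per array was amplified and biotin-labelled with an Affymetrix IVT Express kit and hybridized to Affymetrix mouse genome arrays. The deposited values are log2 expression of 45101 probe sets on 6 arrays. Per the submitters' processing notes the authors used RMA, which subtracts background, normalizes between arrays and summarises probes, in R 3.0.1; its settings are not given in the sources used here. The log2 scale was read from the values, which run from 6.10 to 15.31. Array medians lay between 7.79 and 7.80, while the 95th percentile ran from 11.46 to 11.65, so the arrays are centred but not equal in spread. The lowest values are high for log2 intensities. Scanner files were not used here, and the values were taken as deposited.

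Probe sets were named through the platform annotation supplied with the value table, with symbols updated by Entrez identifier from a RefSeq gene table where possible (34741 probe sets). After 64 control probe sets were set aside, 34945 probe sets had exactly 1 gene symbol, 932 had several and 9160 had none; probe sets with several symbols were not named. Of 18193 genes, 9010 had more than 1 probe set, and the probe set with the highest mean over the 6 arrays stood for the gene. Genes above their array's median on at least 2 arrays were tested, which left 11743. Probe sets of a gene can disagree: those of Egr2 gave -0.84 and -0.62 at the high dose, while those of Malat1 ran from -0.63 to -0.08 and those of Homer1 from -0.88 to -0.01. No genome build is named in the sources, so no coordinates are given.

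Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. Each comparison was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), on all 6 arrays with 1 coefficient per dose group and no further term, since the series describes grouping by dose regardless of side. The dose trend used the dose as a number, and the left against right comparison had dose group as a term. The variance prior had infinite degrees of freedom in the left against right fit and in many alternatives of the comparisons between dose groups. These were fits with added terms, the stricter filter, the first date's arrays, and most fits without 1 array. All genes then shared 1 estimate of the spread, and p-values from those fits rest on that shared estimate. For the dose trend this held with date, side and date, or RIN as terms and on the first date's arrays, but not in fits without 1 array. With trend and robust settings the prior follows the expression level, so genes do not share 1 estimate. Of 30 fixed gene lists, covering monoamine and plasticity pathways, cell types, hippocampal subfields, neighbouring tissues and cell maintenance, 28 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list moves on balance 1 way. The red blood cell list and that of noradrenaline and dopamine receptors had 2 tested genes each and were not tested; at the high dose Bpgm and Hbb-b2 of the first list had log2 fold changes of 0.11 and -0.014, and Drd1 and Adra2c of the second -0.32 and -0.049.

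The genes named in each dose comparison are up to 12 higher and 12 lower genes past the threshold with the largest change; if fewer than 24, the remainder from genes with an unadjusted p under 0.01 whose values in the 2 groups do not overlap, given as values and not as changes; a panel of 22 genes fixed in advance; and up to 4 members of each list with the largest moderated statistic. For the trend and for left against right, up to 6 higher and 6 lower genes were named likewise. Members of a list that passed over the list alone are named from the list test. Differences between arrays of 1 date are plain subtractions. Over the tested genes, the difference of replicate 2 from replicate 1 had a correlation of 0.540 between control and high dose, 0.0765 between control and low dose, and 0.133 between low and high dose. In the labels the replicate number equals the hybridization date for control and high dose, which pairs those arrays by date, whereas both low dose arrays share 1 date.

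No 2 arrays held identical values. The fits were tested on simulated arrays with the real genes' levels and spread, with 200 of 11743 genes changed, in 10 runs. For high dose against control, 90.1% of changes of 0.5 log2 and 100% of those of 1 log2 were recovered, with 11.7 false among 201.8 calls on average; for low dose against control the shares were 89.4% and 100%, and for high against low dose 89.8% and 100%. With the date as a block 89.2%, 76.1% and 75.2% of the changes of 0.5 log2 were recovered in the same order. These shares hold for 200 changed genes, which makes the adjusted threshold less strict than when few genes differ. In the real high dose against control fit, Fos at -0.59 (limma adjusted p = 0.0747) and Egr1 at -0.54 (0.205) did not pass. Alternatives covered the filter, the choice of probe set, centring, the variance settings, date, side, RIN and replicate number as terms, the arrays in the fit, and leaving out each array. A fit of the 4 arrays of the first date and quantile normalization of the deposited columns were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.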

Results

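Gene expression was measured in the hippocampus of male DBA/2 mice that took up venlafaxine with their drinking water for 30 days. Venlafaxine is an antidepressant that blocks the reuptake of serotonin and noradrenaline. The daily doses were 0 (control), 30 (low dose) and 100 (high dose) mg per kg body weight, with 10 animals in each dose group. RNA was combined within each dose group by brain side, so that every group contributed 1 pool of left and 1 pool of right hippocampi, and each pool was hybridized to 1 Affymetrix mouse genome array, 6 arrays in all. Both low dose arrays, control replicate 1 and high dose replicate 1 were hybridized on the first date, and control replicate 2 and high dose replicate 2 on the later date. Control replicate 1, low dose replicate 1 and high dose replicate 2 were right pools, and the other arrays left pools. Control and high dose arrays of the same date therefore differ in side, and those of the same side differ in date. The RNA integrity number (RIN) was 8.7 and 7.9 in the control pools, 9.1 and 8.9 in the low dose pools and 8.5 and 8.2 in the high dose pools. The labels do not say that the 2 pools of a group came from separate animals, and left and right pools may come from the same brains, so p-values measure only the spread between these pools, which may be technical. The number of arrays limits the precision of every value given here. The arrays of the same date resembled each other more than those of the same dose: over all probe sets the 2 control arrays had a Pearson correlation of 0.995, and control replicate 2 and high dose replicate 2, which share the later date, one of 0.997.

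The first comparison asked which genes differed between the highest dose and no drug. Genes induced by neuronal activity were lower at the high dose. Egr2, a zinc finger transcription factor of the immediate early class, fell from a log2 level of 8.85 ± 0.30 (SD, n = 2) in the controls to 8.01 ± 0.0014 (SD, n = 2) at the high dose, a log2 fold change of -0.84 (SE 0.12, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00226) or 1.79-fold. It was the 1 gene of 11743 past the threshold, and 324 genes had an unadjusted p under 0.05, where chance alone gives 587. Of the 20 immediate early genes fixed as a list, 1 fell when adjusted over all genes and 12 fell when adjusted over the list alone, namely Egr2, Fos, Egr1, Nr4a1, Arc, Egr3, Dusp1, Fosb, Ier5, Nr4a2, Fosl2 and Junb. For 15 of the 20 both high dose arrays lay below both control arrays, where chance puts 33.3% of genes apart in either direction. The list's median log2 fold change was -0.35 and camera with its preset correlation gave an adjusted p of 3.84e-23 over 28 lists. The call was lost with an estimated correlation (adjusted p = 0.245 with an estimated correlation), and fry gave an adjusted p of 0.230.

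Within each hybridization date the immediate early list lay lower at the high dose, with a median difference of -0.34 between the arrays of the first date and -0.32 between those of the later date. Paired by side, the median difference was -0.17 on the left and -0.39 on the right. With the date as a block, Egr2 kept its call (adjusted p = 1.17e-15) and 44 genes passed, 3 higher and 41 lower. They included Fos (log2 fold change -0.59, adjusted p = 6.1e-07 with the block, 0.0747 without), Egr1 (-0.54, 1.66e-05 and 0.205), Nr4a1 (-0.51, 7.16e-05 and 0.275), Arc (-0.50, 0.000104 and 0.275), Dusp1 (-0.42, 0.00405 and 0.668) and Egr3 (-0.43, 0.00289 and 0.640). Arc encodes a protein of active synapses, Nr4a1 an orphan nuclear receptor and Dusp1 a phosphatase that acts on MAP kinases. Npas4, another activity-induced factor, had a log2 fold change of 0.11 (adjusted p = 1.00). Both dates hold 1 control and 1 high dose array, so neither allows a test of its own; a fit of the first date's 4 arrays, in which 14 genes passed, takes all its spread from the 2 low dose arrays, and this holds for every first-date result below.

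**Figure D1:**
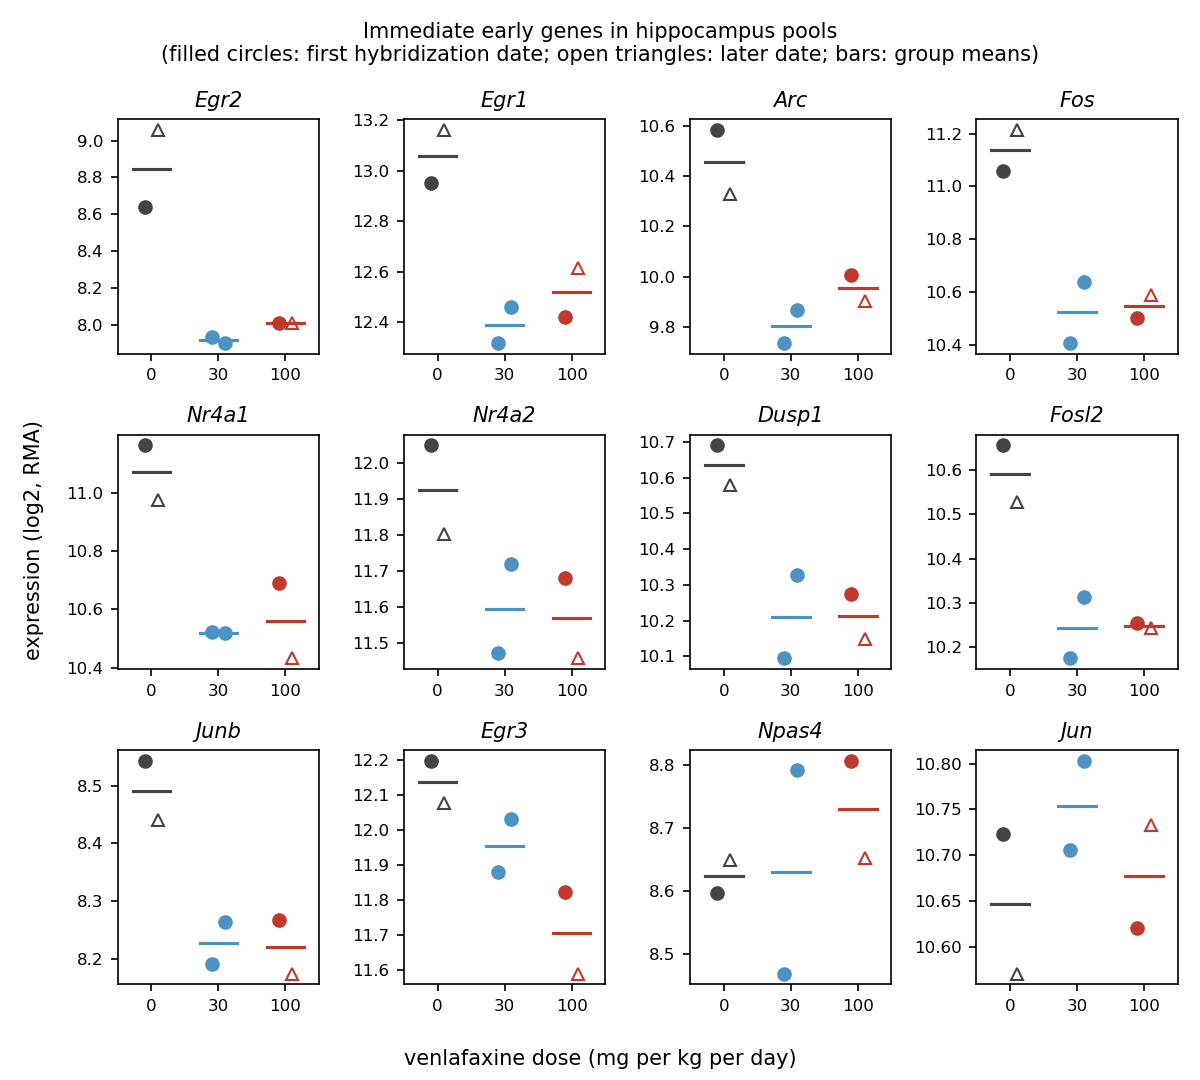
Log2 RMA expression (vertical axes) of 12 of the 20 immediate early genes (10 that were lower at both doses, and Npas4 and Jun) against venlafaxine dose in mg per kg per day (horizontal axes), with a filled circle for each array of the first hybridization date, an open triangle for each of the later date, and a bar at the mean of the 2 arrays of a group. The Egr2 values of the 4 treated arrays sit between 7.90 and 8.01, below the control values of 8.64 and 9.06, while Npas4 and Jun show no such order.

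The 23 genes chosen by rule to follow Egr2, among them Fos, Egr1, Nr4a1, Arc, Egr3 and Dusp1, had an unadjusted p under 0.01 and high dose arrays that did not overlap the control arrays. None passed over all genes without the date, and all 23 did with the date as a block. The block left their fold changes as they were and gave all genes 1 shared spread, so its p-values rank genes by size of change. The 23 were picked by that size, so their passing adds no support of its own. Malat1, a nuclear noncoding RNA, had a log2 fold change of -0.61 (SE 0.14, adjusted p = 0.353, or 2.42e-07 with the block), with 12.52 on high dose replicate 2 against 13.17 on replicate 1. Tra2a, a splicing factor, had -0.52 (adjusted p = 0.850, or 4.36e-05 with the block), and Nfil3, a repressor tied to the circadian clock, -0.48 (0.353 and 0.000242). The other probe sets of Tra2a ran from -0.23 to -0.03. Values between -0.42 and -0.38 were measured for Gpr6, Fosb, 9530059O14Rik, Mtcl1, Cdkn1a, Med20, Atp2b4, Tnfrsf25, Gfod1, Arpp21, Kmt2a and Klf10. Only 2 of the 23 were higher at the high dose. Gh, the growth hormone gene, had a log2 fold change of 0.45 (SE 0.10, adjusted p = 0.353, or 0.00115 with the block), and Zic1, a transcription factor, 0.41 (0.850 and 0.00623).

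Markers of some tissues near the hippocampus also shifted at the high dose, while the thalamus list did not pass (median -0.09, camera adjusted p = 0.0827). All 9 tested striatum markers had lower means, with a median of -0.31 (camera adjusted p = 7.34e-11; adjusted p = 0.583 with an estimated correlation), and 7 of them fell when adjusted over the list alone and 0 over all genes, among them Tac1 (-0.38), Penk (-0.39) and Pde10a (-0.33). Paired by date, the difference was larger on the later date, with a median of -0.50 there and -0.10 on the first date. Paired by side, the median was -0.26 on the left and -0.32 on the right. The neocortex list fell too, with a median of -0.20 (0.000262; adjusted p = 0.661 with an estimated correlation), 0 of 10 members past the threshold over all genes or over the list alone, and medians of -0.18 and -0.23 on the first and the later date. Paired by side, the neocortex medians were -0.05 on the left and -0.27 on the right. The date block, which cannot change differences between high dose and control, left both the striatum and the neocortex call in place (camera adjusted p = 3.02e-15 and 1.38e-05). On the first date alone the neocortex list did not pass (0.0680). Tbr1 had -0.38 (adjusted p = 1.00, or 0.0162 with the block) and Lamp5 -0.28 (1.00 and 0.224).

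Choroid plexus markers were higher on average, with a median of 0.16 (camera adjusted p = 3.54e-12; adjusted p = 0.661 with an estimated correlation) and 0 of 15 members past the threshold either way of adjusting. Paired by date, that direction held only for the later date, where the median difference was 0.55, while it was -0.16 on the first date. Paired by side, the median was 0.11 on the left and 0.29 on the right. The call ended without high dose replicate 2. Ttr, the most abundant of these markers, ranged from 14.82 to 15.31 over the 6 arrays with no order by dose. Meningeal and fibroblast markers such as Fmod (0.36) and Col3a1 (0.32) were higher as a list on both dates, with a median of 0.19 over both dates, 0.11 on the first and 0.32 on the later date (9.76e-12; adjusted p = 0.583 with an estimated correlation), and 0 of 11 passed singly either way.

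Protein-folding genes fell as a list at the high dose. The 24 tested chaperone and unfolded protein response genes had a median of -0.13 (camera adjusted p = 1.96e-06, or 2.03e-06 with the date as a block; adjusted p = 0.661 with an estimated correlation), and 23 of them had lower means, with 0 past the threshold over all genes or over the list alone. Dnajb1, a cofactor of heat shock protein 70, had -0.36 and Xbp1, a transcription factor of the unfolded protein response, -0.25. Within the dates the medians were -0.19 and -0.11. Circadian clock genes had a median of -0.11 (0.0131; adjusted p = 0.768 with an estimated correlation), with Nfil3, Bhlhe40 (-0.32) and Npas2 (-0.32) falling when adjusted over the list alone and 0 of 17 over all genes. The glutamate receptor list had a median of -0.10 (0.0302; adjusted p = 0.768 with an estimated correlation). Mature dentate granule cell (median 0.07, 0.00312), CA3 and CA2 pyramidal (0.05, 0.0131), interferon response (0.06, 0.0334) and oxidative phosphorylation genes (0.03, 0.0131) lay slightly above the rest of the genes. The dentate and the CA3 and CA2 medians were -0.045 and -0.011 on the first date and 0.20 and 0.15 on the later. The oxidative phosphorylation median was -0.012 on the first date and 0.064 on the later. These medians were thus above 0 on the later date only. On the first date they still lay above the median of all genes, which was -0.085. The estimated-correlation values of the 4 lists in that order were adjusted p = 0.768, 0.661, 0.661 and 0.826. The circadian, glutamate receptor, interferon and oxidative phosphorylation calls ended without control replicate 1 and without high dose replicate 2, the dentate granule call without control replicate 2, and the CA3 and CA2 call without control replicate 2 or either high dose array.

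Of the genes tested in the systems that venlafaxine acts on, none passed the threshold at the high dose. The serotonin transporter gene Slc6a4, whose product is a target of the drug, and the adrenergic receptor genes Adra2a and Adrb1 were not tested, because they did not pass the filter or had no probe set of their own. The same holds for all but 2 of 14 noradrenaline and dopamine receptor genes. Serotonin receptors had a median of -0.08 (camera adjusted p = 0.354), genes of monoamine transport, synthesis and breakdown 0.04 (0.138), and neurotrophins and growth factors -0.05 (0.755). Of a panel of 22 genes, 19 were tested and 0 passed. The noradrenaline transporter gene Slc6a2, whose product the drug also blocks, was among those tested and had a log2 fold change of -0.03. The log2 fold change was -0.14 for the serotonin receptor gene Htr1a, 0.04 for monoamine oxidase A (Maoa), 0.09 for Bdnf, -0.12 for its receptor gene Ntrk2, -0.06 for the glucocorticoid receptor gene Nr3c1, -0.06 for Fkbp5 and 0.01 for the immature neuron marker Dcx. The list of adult neurogenesis genes (adjusted p = 0.662) and those of astrocytes (0.586), microglia (0.832) and oligodendrocytes (0.418) did not pass either, and over the 16 lists that missed the threshold the adjusted p ran from 0.0514 to 0.832. The Egr2 call ended without a filter on dim probe sets (adjusted p = 0.199), with the mean of a gene's probe sets (0.735), after centring (0.936) or quantile normalization (0.858) of the arrays, and without low dose replicate 1 or replicate 2 (1.00 each), although its log2 fold change stayed between -1.05 and -0.63. The count of genes was 178 without control replicate 2, 25 without control replicate 1, 14 without high dose replicate 1 and 7 without high dose replicate 2.

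The second comparison asked what the lower dose did. The same group of activity-induced genes was lower: Egr2 fell by 0.93 on the log2 scale (SE 0.12, limma adjusted p = 0.000394), Egr1 by 0.67 (SE 0.11, adjusted p = 0.0138), Arc by 0.65 (SE 0.11, adjusted p = 0.0138) and Fos by 0.61 (SE 0.11, adjusted p = 0.0193). In each of these 4 genes both low dose arrays lay below both control arrays. The 1 gene that rose was Avp, which encodes the peptide hormone vasopressin, with a log2 fold change of 0.96 (SE 0.17, adjusted p = 0.0193). Its level was 9.32 on low dose replicate 1 and 8.40 on low dose replicate 2, against 7.80 and 8.00 on the control arrays. These 5 genes of 11743 passed, and 390 had an unadjusted p under 0.05. Once the date was a block 21 genes passed, 5 higher and 16 lower, and in the first-date fit, with 1 control array, 18; all 5 genes passed in both.

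Of the 20 immediate early genes, 4 fell when adjusted over all genes and 9 when adjusted over the list alone, the 5 beyond those 4 being Nr4a1, Nr4a2, Dusp1, Fosl2 and Junb. The list's median was -0.20 (camera adjusted p = 5.28e-34; adjusted p = 0.141 with an estimated correlation; fry 0.256). Against the first date's control the median was -0.30, and no low dose array was hybridized on the later date. The list stood higher on that control array (0.28) than on control replicate 2 (0.11). Paired by side, the median was -0.11 on the left, where the arrays differ in date, and -0.34 on the right. For 14 of the 20 genes both controls lay above all 4 treated arrays, where chance gives 6.67%, and in an exact two-sided permutation test of the list's mean over the 15 ways to choose 2 of the 6 arrays p was 0.0667, the smallest value this design allows. The neocortex list fell as well, with a median of -0.12 and -0.20 on the first date (5.28e-09; adjusted p = 0.571 with an estimated correlation), and Ccn2 (-0.61) and Cux2 (-0.34) fell when adjusted over the list alone and 0 of 10 over all genes.

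**Figure D2:**
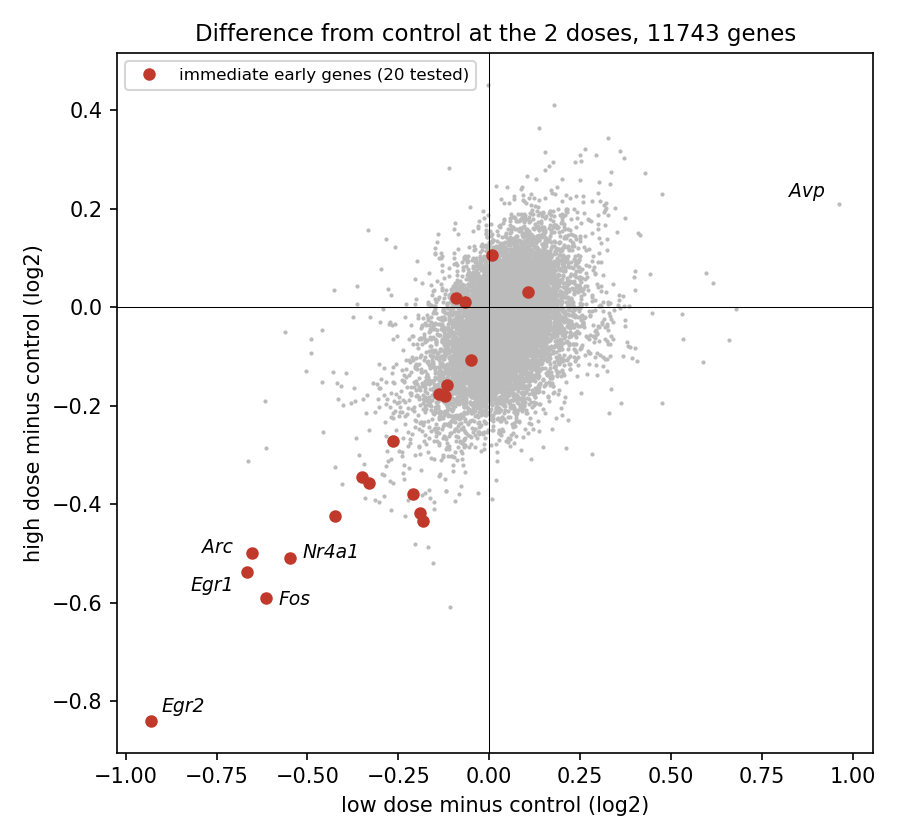
Log2 difference from control at the high dose (vertical axis) against that at the low dose (horizontal axis) for 11743 genes, each a grey point, with the 20 immediate early genes in red. Egr2 lies furthest toward the lower left at -0.93 and -0.84, with Egr1, Arc, Fos and Nr4a1 behind it, and Avp lies to the right at 0.96 and 0.21.

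Myelin genes were higher at the low dose. All 15 tested oligodendrocyte genes had higher means, with a median of 0.30 (camera adjusted p = 1.11e-13; adjusted p = 0.571 with an estimated correlation); 8 rose when adjusted over the list alone, among them Mal (0.34), Mag (0.33) and Cnp (0.29), and 0 over all genes. On the first date the median was 0.14, and with the date as a block the list passed (1.97e-09). Choroid plexus markers had a median of 0.26, and 0.11 on the first date (3.73e-10; adjusted p = 0.807 with an estimated correlation). Kl (0.48) and Igfbp2 (0.41) rose when adjusted over that list alone, and 0 of its 15 members over all genes. Mature dentate granule cell genes had a median of 0.17 (0.00698; adjusted p = 0.868 with an estimated correlation) and did not pass with the date as a block (0.0656). CA3 and CA2 pyramidal genes had a median of 0.20 (0.00364; adjusted p = 0.807 with an estimated correlation), passed with the block (0.00120, median 0.11), and lost the call with the stricter filter (0.0596) and with RIN as a covariate (0.0539, median 0.027). Chaperones, which fell at the high dose, had a median of 0.07 here (0.0344; adjusted p = 0.868 with an estimated correlation), and that call ended after quantile normalization, with the stricter filter, without control replicate 1 and without low dose replicate 2. The dentate granule call ended without control replicate 2.

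Glucocorticoid response genes were placed lower relative to other genes, whose median was 0.04 (median -0.03, 9 members higher and 10 lower, camera adjusted p = 0.00546; adjusted p = 0.868 with an estimated correlation), with Klf9 at -0.40 and Cdkn1a at -0.30, and 0 of 19 passed singly. The median was 0.059 without control replicate 1, which ended the call, and 0.049 with the stricter filter. The striatum list (median -0.08, 0.0344; adjusted p = 0.868 with an estimated correlation) kept its call in 10 of 19 alternative settings. It turned to a median of 0.04 on the first date and without control replicate 2, and to 0.08 with RIN as a covariate, and its call ended without low dose replicate 1, without a filter, with the stricter filter, with the mean of probe sets, and after centring or quantile normalization. A further 19 genes chosen by rule had an unadjusted p under 0.01 and low dose arrays apart from the controls without passing over all genes. The date block let 3 of them pass, Nr4a1 (-0.55, adjusted p = 4.83e-07 with the block, 0.0793 without), Ccn2 (0.000260 and 0.581) and Kl (0.0148 and 1.00). The other 16 did not pass with the block, among them Bsg (0.68), Mlf2 (0.66), Ly6e (0.61), Pfn1 (0.60), Adgra1 (-0.66), Ankrd12 (-0.62) and Thoc2 (-0.56). Probe sets of the last 3 genes disagreed. They ran from -0.66 to -0.09 for Adgra1, from -0.62 to -0.004 for Ankrd12 and from -0.56 to 0.08 for Thoc2. For Mlf2 the later date's arrays read 9.57 and 9.54 and the first date's 10.29 to 10.67.

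Serotonin receptors had a median of 0.04 at the low dose (camera adjusted p = 0.864), monoamine transport, synthesis and breakdown genes 0.08 (0.472) and neurotrophins and growth factors 0.05 (0.769). Outside Fos, Arc and Egr1 the 16 remaining panel genes did not pass, and their log2 fold changes ran from -0.17 for Dcx to 0.26 for the serotonin receptor gene Htr2c. Bdnf had 0.01, Ntrk2 -0.08 and Nr3c1 0.05. Over the 19 lists that did not pass the adjusted p ran from 0.0527 to 0.960. The 5 calls ended without a filter on dim probe sets, with the mean of a gene's probe sets, after centring or quantile normalization, and without low dose replicate 1. Those of Egr2, Egr1, Arc and Fos also ended without low dose replicate 2, and that of Avp with trend and robust settings. Those of Egr1 and Fos ended with RIN as a covariate too, where they had -0.44 and -0.43. Over the settings the log2 fold change ran from -1.14 to -0.63 for Egr2, from -0.77 to -0.44 for Egr1 and from -0.84 to -0.52 for Arc. It ran from -0.73 to -0.43 for Fos and from 0.50 to 1.42 for Avp. Without control replicate 1 the count was 546, without control replicate 2 13, and without either high dose array 22.

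The 2 doses were then set against each other. Limma called 0 genes at an adjusted p under 0.05, and 729 had an unadjusted p under 0.05. Protein-folding and myelin genes separated the doses as groups. Of the 24 chaperone and unfolded protein response genes 23 had lower means at the high than at the low dose, with a median of -0.24 (camera adjusted p = 5.3e-11, or 6.08e-21 with the date as a block; adjusted p = 0.973 with an estimated correlation), and of -0.13 without low dose replicate 2. Adjusted over the list alone 9 of them fell, among them Hspa1b (-0.58), Hspb1 (-0.48), Hspa1a (-0.41) and Sdf2l1 (-0.34), and 0 over all genes. All 15 oligodendrocyte genes had lower means at the high dose (median -0.26, 5.9e-10, or -0.17 and 2.15e-08 with the block, and a median of -0.16 without high dose replicate 2; adjusted p = 0.973 with an estimated correlation), with 7 falling over the list alone, such as Mog (-0.43) and Mag (-0.40), and 0 over all genes. Striatum markers were lower (median -0.23, camera adjusted p = 0.000209, adjusted p = 0.973 with an estimated correlation), with Ppp1r1b (-0.42) falling over the list alone. Over the alternative settings the striatum median ran from -0.38 to -0.077, and the call ended in 3 of 19. Meningeal and fibroblast markers were placed higher relative to other genes (median 0.07, camera adjusted p = 4.39e-05, adjusted p = 0.973 with an estimated correlation). Of these, 6 members were higher and 5 lower, and the median was -0.072 without low dose replicate 1, which ended the call.

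The immediate early list did not separate the doses, with a median of -0.00299 (camera adjusted p = 0.0556), and Fos differed by 0.02, Egr2 by 0.09 and Arc by 0.15. Relative to all other genes, whose median was -0.04, the block put that list higher at the high dose (0.0159; adjusted p = 0.973 with an estimated correlation without the block), as did the first-date fit (0.00154). Against the first date's control its medians were -0.34 at the high and -0.30 at the low dose. The 24 genes chosen by rule were led by Avp (-0.75, adjusted p = 0.529), Mlf2 (-0.72), Get3 (-0.70), Bsg (-0.68) and Psmb7 (-0.67), and held the synaptic vesicle genes Syp (-0.54) and Vamp1 (-0.46), the proprotein convertase inhibitor Pcsk1n (-0.51), Map1a (-0.56), Malat1 (-0.50) and Pkm (-0.50); Gh (0.45) and Rpl27a (0.49) were the 2 that were higher at the high dose. The other probe set of Map1a gave -0.05. With the date as a block 3 genes passed, Avp (adjusted p = 2.13e-12), Hspa1b (0.00439) and Pmch (-0.46, 0.00312), which encodes melanin-concentrating hormone, and all 3 were lower at the high dose. These p-values rest on 1 spread shared by all genes. They leave out that the 2 low dose arrays of Avp lay far apart, and its low dose call ended without low dose replicate 1. The other 21 did not pass with the block. In the first-date fit, where the high dose is 1 array and the spread is that of the low dose pair, 9 genes passed. The count was 152 without either control array, 117 without high dose replicate 1 and 1 without high dose replicate 2.

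**Figure D3:**
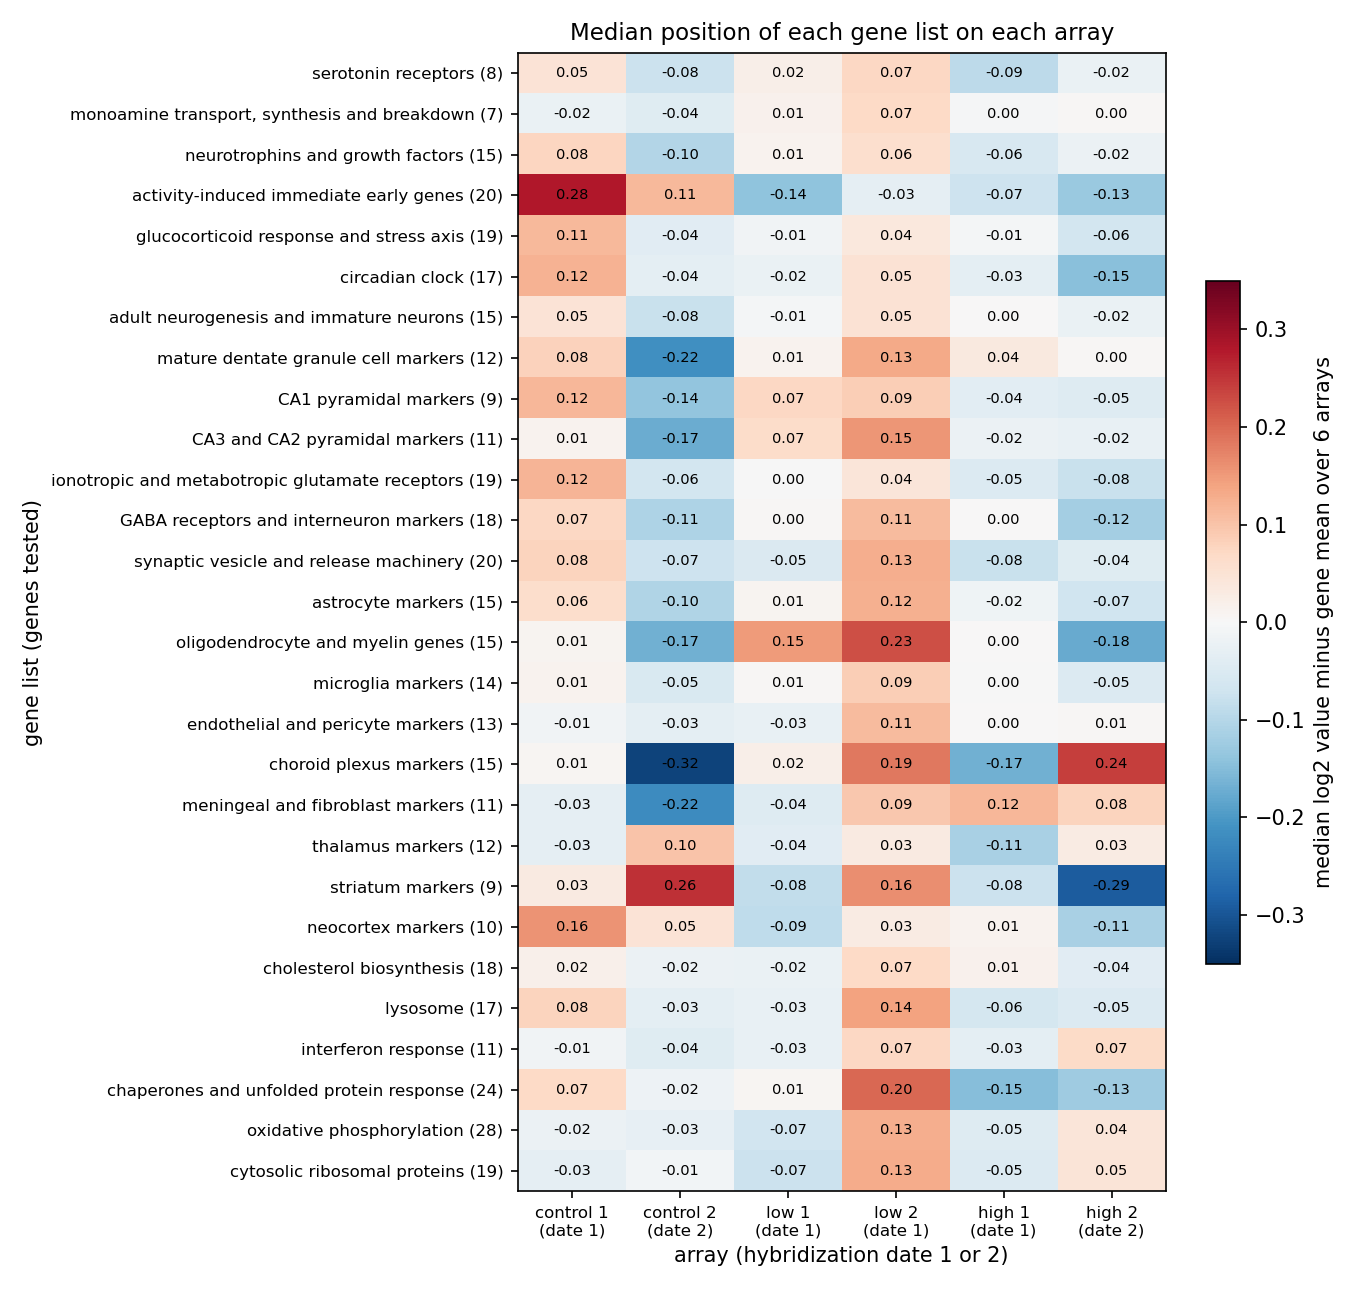
Median position of 28 gene lists (rows, with the number of genes tested) on the 6 arrays (columns, with the hybridization date), as log2 value minus the gene's mean over all arrays, printed in each cell and coloured from blue (lower) to red (higher). The immediate early list stands at 0.28 and 0.11 on the control arrays and between -0.14 and -0.03 on the treated ones, whereas choroid plexus markers run from -0.32 on control replicate 2 to 0.24 on high dose replicate 2.

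A linear trend over the doses of 0, 30 and 100 mg per kg per day gave 0 genes with limma, and 398 genes had an unadjusted p under 0.05. Given the date block 45 genes passed, 4 higher and 41 lower, and in the first-date fit 77. The genes named by rule were Gh, with a slope of 0.49 log2 per 100 mg per kg per day, Zic1 (0.40) and the collagen gene Col3a1 (0.30), which were higher with dose, and Malat1 (-0.63), Tra2a (-0.52), Nfil3 (-0.47), Gfod1 (-0.42), Egr3 (-0.42) and Mtcl1 (-0.40), which were lower. All 9 had an adjusted p of 0.998 without the block and passed with it, at 0.0450 or below. The p-values with the block rest on 1 spread shared by all genes, and the 9 were picked by the size of their slope. The count was 140 without control replicate 2.

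Left and right pools were compared with dose group as a term, since each group held 1 of each. Limma called 0 genes, and 40 had an unadjusted p under 0.05, where chance alone gives 587. The left and right arrays of the control and high dose groups also differ in date, so date differences add to the spread of this fit. Penk, which encodes enkephalin peptides, was the 1 gene named by rule, 0.33 higher on the left on the log2 scale (SE 0.11, adjusted p = 1.00), and had 0.886 with the date as a block. The count was 2 without either control array and 1 without either high dose array.

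Across the 11743 genes the changes at the 2 doses had a Pearson correlation of 0.439. This agreement of low dose and high dose changes ran from 0.107 without high dose replicate 1 to 0.759 without control replicate 1. Genes are not independent replicates, and both comparisons use the same control arrays: 100 simulations of unchanged groups with the measured date effect gave a mean of 0.403 (SD 0.00678, highest 0.417). The covariance was 0.00405 against a simulated 0.00428, a difference of -0.000228. The 2 control arrays cannot be divided between the comparisons, so part of any overlap may come from them. Egr2 was the 1 gene called lower at both doses, where independent calls would share 0.000341. With the date as a block 12 genes were called lower at both doses, where independent calls would share 0.0559. In 100 simulations of unchanged groups 0 calls were shared, and as many top genes as were called shared 1.44 on average and 5 at most. Both doses there used the same simulated controls, but the simulated genes varied independently. The simulations therefore cannot show how often genes that move together would be shared. The 12 were Arc, Arpp21, Dusp1, Egr1, Egr2, Fos, Nr4a1, Nr4a2, Sbk1, Tbr1, Tra2a and Tshz3. For Tra2a the low dose arrays read 10.69 and 10.66, below control replicate 1 (11.10) but above control replicate 2 (10.56). The probe sets of Arpp21 ran from -0.64 to -0.05 at the low dose and from -0.39 to -0.06 at the high dose. No gene was called higher at both.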

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

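The tests of explanations in this part were chosen after the results were seen. Groups of 2 arrays are too small for a rule on single outlying samples, so what stands here are 4 gene lists whose high and low dose groups differed by a test of the difference itself. Each of these was past the threshold with camera's preset correlation and lost the call with an estimated correlation (adjusted p = 0.973 for all 4).

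Chaperone and unfolded protein response genes were lower at the high than at the low dose (median -0.24, camera adjusted p = 5.3e-11). The hybridization date as the whole source is argued against by a median of -0.21 with the date as a block (bootstrap 95% interval over members -0.29 to -0.11, camera adjusted p = 6.08e-21), and unequal spread between arrays by -0.17 after quantile normalization (-0.20 to -0.091, adjusted p = 3.42e-10), though it may be part of the source; these p-values use the preset correlation. A single low dose array cannot be ruled out: without low dose replicate 2, which carried the highest position of the list (0.20), the median was -0.13 (-0.19 to -0.074), but the low dose is then 1 array and the spread comes from the other groups. The rule, an interval below 0 and a call that is kept, is 1 of 4 versions set after values were known; an interval below -0.1 would have left the spread undecided, and intervals that treat genes as independent are too narrow. The dose itself was not tested apart from differences between pools.

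Oligodendrocyte and myelin genes were lower at the high than at the low dose (median -0.26, camera adjusted p = 5.9e-10), with medians of -0.17 with the date as a block and -0.16 without high dose replicate 2. Striatum markers were lower (median -0.23, adjusted p = 0.000209), and that call ended without low dose replicate 2, without high dose replicate 2 and on the first date alone. Meningeal and fibroblast markers were higher relative to other genes (median 0.07, adjusted p = 4.39e-05), with 6 members higher and 5 lower, and without low dose replicate 1 the call ended and the median turned to -0.072.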

How the results depend on the processing

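The fit of the first date's arrays alone and quantile normalization were chosen after seeing the data. The former has 1 control and 1 high dose array, so its spread is that of the low dose pair. Counts of genes past the threshold moved with nearly every choice, and the cause was not tested unless stated; dim probe sets near the high floor of these values limit what the arrays can show. For high dose against control the count of 1 became 0 without a filter, with the mean of a gene's probe sets, with every probe set tested on its own, after centring, after quantile normalization and with only the 2 groups compared. It became 4 with the stricter filter, 14 with trend and robust settings, 44 with the date as a block, 3 with side as a covariate, 10 with side and date as terms, 39 with RIN as a covariate and 14 on the first date alone. Leaving out 1 array gave 0 to 178. For low dose against control the count of 5 became 0 without a filter, with mean or single probe sets, after centring and after quantile normalization. It became 19 with the stricter filter, 17 with trend and robust settings, 21 with the date block, 17 with side, 9 with side and date, 20 with RIN, 22 with only the 2 groups and 18 on the first date; leaving out 1 array gave 0 to 546. For high against low dose the count of 0 became 19 with the stricter filter, 25 with trend and robust settings, 3 with the date block, 11 with side, 1 with side and date, 4 with RIN, 152 with only the 2 groups and 9 on the first date, and 0 to 152 with 1 array left out. The dose trend went from 0 to 45 with the date block, 30 with side and date, 34 with RIN and 77 on the first date, and to 0 to 140 with 1 array left out. Left against right went from 0 to 17 with RIN, and to 0 to 2 with 1 array left out.

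With the replicate number as a block the counts were 10 for high dose against control, 32 for low dose against control and 45 for high against low dose, and 0 for the trend and for left against right. The number pairs control and high dose arrays, by hybridization date, and not the low dose arrays, which share 1 date; Egr2 kept its call with the block, and no count of gene lists moved by more than 1.5 times with it (13, 10 and 4).

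Counts of gene lists for high dose against control (12) and low dose against control (9) stayed within 1.5 times under the other fits, except for 16 lists at the low dose without low dose replicate 1, in a range of 8 to 16 with 1 array left out. For high against low dose the count of 4 became 7 without a filter and with the stricter filter, 11 with the date as a block and with side and date, 9 with RIN, 9 on the first date and 4 to 9 with 1 array left out; after quantile normalization it was 5, 2 higher and 3 lower, against 1 higher and 3 lower. With an estimated correlation and with fry the count was 0 in all 3 comparisons; fry's test for change in either direction called 1 list at the high dose (adjusted p = 0.0360) and 1 at the low dose (0.0235). Over 25 list calls and 474 list values under the alternatives other than those 2 tests, 417 kept the call, 52 lost it and 5 changed direction. At the high dose the circadian and glutamate receptor calls ended with the stricter filter and the mean of probe sets, the CA3 and CA2, interferon and oxidative phosphorylation calls without a filter, and the interferon call also with the mean of probe sets and after centring or quantile normalization, the last of which ended the oxidative phosphorylation call too. On the first date all of these but oxidative phosphorylation were lost, and so was the dentate granule call. At the low dose the dentate granule call also ended with side and date as terms. Those 5 were the choroid plexus list at the high dose on the first date (median -0.16), the mature dentate granule cell markers list at the low dose with RIN (-0.070), and the striatum markers list at the low dose with RIN (0.079), without control replicate 2 (0.040) and on the first date (0.040). With 1 array left out the striatum list at the low dose ran from -0.19 to 0.044. The agreement of low dose and high dose changes, a correlation over genes, ranged from 0.107 without high dose replicate 1 to 0.759 without control replicate 1. Lists were not tested on single probe sets, and side could not be added as a term to the left against right fit. Of the named genes' values, none changed direction past the threshold. Those that gained it numbered 156 at the high dose, 170 at the low dose, 221 between the doses and 36 for the trend, and those that lost it 7 at the high and 32 at the low dose.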

Other observations

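Avp, Pmch and Gh, which encode peptide hormones, were picked after the results were seen, and in each the 2 arrays of 1 dose group lay above the other 4. The vasopressin gene Avp read 9.32 on low dose replicate 1 and 8.40 on low dose replicate 2, and between 7.80 and 8.21 on the other 4 arrays. Pmch read 8.07 and 8.40 on the low dose arrays and between 7.71 and 7.99 elsewhere. Gh read 8.12 and 8.32 on the high dose arrays and between 7.71 and 7.83 elsewhere, and 3 further probe sets of Gh gave high minus control differences of 0.72, 0.92 and 0.79, all near the floor of the arrays. Many genes differed between the hybridization dates within dose groups: with dose group in the model 818 genes passed, 145 higher and 673 lower on the later date, led by A330076H08Rik (1.37), Cplx2 (0.85), Srrm2 (0.80) and Mlf2 (-0.78). These calls rest on 1 spread shared by all genes. RIN was also lower on the later date, at 7.9 against 8.7 in the controls and 8.2 against 8.5 at the high dose. Date and RNA integrity therefore cannot be told apart here. Over all genes the median absolute date difference was 0.09, against 0.06 for either dose.

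The tests below were chosen after the results were seen, except for the date block and the count over splits of the arrays. Immediate early genes were lower in both dose groups than in the controls. The hybridization date as the whole source is argued against by medians from the control of the same date. They were -0.34 (bootstrap 95% interval over members -0.41 to -0.24) and -0.32 (-0.46 to -0.089) at the high dose and -0.30 (-0.47 to -0.16) at the low dose. With the date as a block, a fit fixed before the data were seen, the list kept its call (camera adjusted p = 1.74e-31 at the high and 1.93e-49 at the low dose, with the preset correlation). Without the block, the adjusted p was 0.245 and 0.141 with an estimated correlation and 0.230 and 0.256 with fry. Each date holds 1 control and 1 high dose array, so the block cannot change the high dose differences. The kept call at the high dose therefore adds nothing against the date. The rule, intervals below 0 and a call that is kept, is 1 of 4 versions set after values were known; intervals below -0.1 would have left the date undecided, and the intervals ignore that genes move together. With RIN as a covariate the medians were -0.36 at the high and -0.39 at the low dose (intervals -0.44 to -0.17 and -0.48 to -0.15). That slope rests mostly on the control pools, which also differ in date and side, so this fit cannot exclude RNA integrity. At the high dose RIN (8.5 and 8.2) lay between the controls' 8.7 and 7.9, while 15 of 20 genes lay below both controls on both arrays. This argues against RNA integrity as the whole source there. At the low dose RIN (9.1 and 8.9) lay above both controls, and RNA integrity stays open. Egr1 and Fos at the low dose lost their calls with RIN as a covariate, going from -0.67 to -0.44 and from -0.61 to -0.43. Neocortex tissue in the control pools cannot be told apart from a change within the hippocampus: the immediate early list fell further than the neocortex markers by -0.15 at the high dose (-0.31 to 0.06) and by -0.08 at the low dose, and of 12 neocortex genes 10 were above the filter in these hippocampus pools, 2 stand on another list, and Mef2c, the brightest, read 11.78 to 12.17. A response to venlafaxine, and differences in arousal, handling or time of killing between the groups, may each be the source and were not tested.

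Choroid plexus markers differed between pools, and what set them apart stays open. For the high dose pools dose stays open, because the 2 ways of pairing the arrays differ. Paired by date, which crosses side, 1 of 15 markers had the same sign of the high dose against control difference on both dates, with medians of -0.16 and 0.55. Paired by side, which crosses date, the medians were 0.11 on the left and 0.29 on the right, with 13 and 15 of 15 markers higher. For the low dose pools dose stays open too. There 15 of 15 markers were higher in their mean than on the control array of the same date (median 0.11). The call was lost with an estimated correlation (adjusted p = 0.807) and with fry (0.740), and on low dose replicate 1 alone 7 of 15 were higher. Unequal amounts of that tissue could be the source and cannot be told apart from other sources: 14 of the 15 markers moved the same way on the first date and 15 on the later, but markers so closely correlated move together whatever the source. All 15 tested markers of 17 were above the filter and none stands on another list; Ttr, the most abundant, read 14.82 to 15.31.

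For left against right, 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes and the highest of the others 348. That 10 of 10 gave at least as many as the real one is certain when the real count is 0. The 2 splits with 348 part only the control arrays and, with dose group as a term, are the same fit. Their count points to a structure of the samples in that pair. The control arrays differ in date, and splits that part the high dose arrays by date gave 43. Splits that part both pairs by date gave 82 and 1, but they also part the low dose arrays, which share 1 date. A date term with dose group in the model leaves those together and gave 818 genes. The replicate differences of control and high dose had a correlation of 0.540. Both values go with the date as that structure. RIN was also lower on the later date in both groups, so the date alone is not shown to be the source.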
